A study of Homo sapiens with 12 samples.

How the data were processed

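Messenger RNA was profiled in 12 human libraries, 3 in each of 4 groups. Per the labels, every library came from liver cells of the line HepG2 or of a line labelled HuH, and each line had a P group and an R group. The R labels carry a number, 250 nm in HepG2 and 55 nm in HuH. Neither P, R nor the number is spelled out in the sources used here, so R is described only as the group set against P of the same line. Per the labels' protocols, total RNA was isolated with an RNeasy kit, treated with DNase, and carried through mRNA separation, fragmentation and complementary DNA synthesis. Whether the libraries keep strand is not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart.

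The deposited table gives raw counts per Ensembl gene, 1 count column per library, per the file headers. The submitters' processing notes name HISAT2 and GRCh38, without a version. The counter and the annotation release are not given in the sources used here. The authors' FPKM columns stand beside the counts, per the file headers. Over the 10006 genes with at least 50 counts in every library, FPKM equalled the count divided by 1 length per gene and by the total of the library, with a largest deviation of 0.00174%. The FPKM values are thus scaled by total count. The table held 50868 genes, of which 20129 had no count in any library. It held 575 rows that share a symbol with another row, which were kept apart by their Ensembl identifier. No row lacked a gene name. Totals ran from 14538046 to 19972120 counts per library.

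Genes were tested with edgeR 4.0.16 in R 4.3.3, by its quasi-likelihood test (glmQLFit, glmQLFTest) on the counts, with TMM scaling, the filterByExpr filter and 1 mean per group in a single fit of all 12 libraries, which left 8 residual degrees of freedom. The filter left 17063 genes. Adjusted p-values are Benjamini-Hochberg values over these genes, and a gene with an adjusted p under 0.05 counts as changed. The contrasts were R against P in HepG2, R against P in HuH, the difference of these 2 changes (HuH minus HepG2), and HuH P against HepG2 P. Overlap of the calls in the 2 lines was set beside the overlap of independent lists and tested with Fisher's exact test, two-sided. Levels are TMM-scaled CPM (each count over the effective library size, times 1e6), as mean ± SD over 3 libraries per group. Fold changes are fitted values with their standard error (SE). Where a group had 0 counts in all its libraries, the fold is given as a bound against a floor of 3 counts per library. In the smallest library of the group, this floor came to between 0.161 and 0.217 CPM. At this depth, genes below that level cannot be told from absent ones. Where a group held 1 to 3 counts in all, the ratio is given with its exact 95% interval, or the levels alone. Intervals and floors cover counting error only.

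A set of 30 gene lists was written for liver cells, drug response and the subjects of the series title, with markers of other cell types. They were ABC transporters, solute carriers for drug uptake, cytochromes P450 and other phase I enzymes, phase II conjugation enzymes, NRF2 target genes, SKP2 and its cell cycle partners, glycolysis and lactate, receptor tyrosine kinases and their ligands, hepatocyte secreted proteins and liver transcription factors. Further lists were fetal liver, progenitor and biliary markers, epithelial to mesenchymal transition, S and G2/M phase genes, p53 target genes, apoptosis regulators, the unfolded protein and integrated stress response, cholesterol synthesis and uptake, fatty acid synthesis and oxidation, interferon-stimulated genes and hypoxia-induced genes. The last were Wnt and beta-catenin target genes, metallothioneins and heat shock proteins, tubulins and microtubule-associated proteins, DNA repair and topoisomerases, inflammatory cytokines and NF-kB targets, gastric epithelium markers, fibroblast and stellate cell markers, endothelial and blood cell markers, mitochondrially encoded genes and replication-dependent histones. Each list with at least 5 tested members was tested with camera (limma 3.58.1) on voom values, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 30 lists. Members were also counted as higher or lower by the gene test, adjusted over all genes and adjusted over the list alone. Some genes stand in more than 1 list, such as SLC2A1 in glycolysis and hypoxia and CDKN1A among SKP2 partners and p53 targets. Tests of such lists are not independent of each other.

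The groups, the tests, the lists, the rule for naming genes and all but 1 of the alternatives were fixed before the data were examined. The rule took, for R against P in each line, the 10 highest and 10 lowest fold changes among changed genes with at least 5 CPM in the higher group and no overlap between the 3 P and 3 R libraries. It took the 3 members of each list with the lowest adjusted p, the 5 highest and 5 lowest genes of the other comparisons, and SKP2, ERBB2 and ABCB1 in any case. Y-linked genes and XIST were left out. In all, 208 genes were named. The camera test of the difference between the lines, the camera test on log2(FPKM + 1) and the search for runs of neighbouring genes were chosen after the data were seen.

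The alternatives were DESeq2 size factors in edgeR, DESeq2 1.42.0, no filter on low counts, a filter of 1 CPM in all libraries of a group, only the 6 libraries of a comparison, a 2-fold threshold, the replicate number as a block, leaving out each library, and limma on log2(FPKM + 1) and log2(FPKM + 0.1). For the FPKM tests, a gene needed a value of at least 1 in at least 3 libraries. The lists were also tested with a correlation estimated from the residuals and with fry. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

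The tests were checked on simulated counts for the 17063 genes, drawn from negative binomial distributions with each gene's own dispersion and the sizes of the real libraries. The compared groups were given equal means, and 200 genes of at least 1 CPM were then changed in each comparison. For R against P in HepG2, edgeR recovered 40.3% of the genes changed 1.5-fold, 65.7% of those changed 2-fold and 97.0% of those changed 4-fold, and 4.93% of its calls were false. For HuH the shares were 29.9%, 79.1% and 98.5%, with 7.38% false. For the difference between the lines they were 7.46%, 59.7% and 75.8%, with 4.04% false. For HuH P against HepG2 P they were 37.3%, 82.1% and 97.0%, with 4.00% false. When a simulated 1.5-fold rise was given to the cholesterol list, camera called that list in both lines, and called 0 others among the 29 lists run. Genes were drawn independently of each other. The simulation therefore cannot show how camera with its preset correlation behaves on correlated genes. Only 200 genes were changed, in random directions, whereas 50.4% of genes were called in HepG2 and 39.9% in HuH. The shares of false calls therefore do not cover errors of scaling when so many genes differ.

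Coordinates are those of the deposited table on GRCh38. Of the tested genes on the chromosomes from 1 to 22 and X, 95.9% had the same start in the GENCODE annotation used as reference. Runs of changed genes were searched in windows of 15 neighbouring tested genes against 1000 permuted gene orders.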

Results

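The data comprised gene counts from 12 human messenger RNA libraries, 3 in each of 4 groups. HepG2, a line from a human liver tumour, gave a P group and an R group whose label carries 250 nm. A liver line labelled HuH gave a P group and an R group whose label carries 55 nm. The labels spell out neither P, R nor the number. The series title and design text are about gastric cancer cells, thioridazine, trastuzumab, SKP2 and glycolysis, whereas all 12 libraries are labelled as liver lines, and the sources used here do not say how they relate. Library totals ranged from 14538046 to 19972120 counts. Levels are TMM-scaled CPM (each count over the effective library size, times 1e6), mean ± SD over n = 3 libraries per group. Nothing in the labels says that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

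The line set most of the variance between libraries, and P and R separated within each line. The first principal component held 81.1% of the variance and parted HepG2 from HuH. The second, with 7.58%, parted P from R in the same direction in both lines, and the third, with 5.57%, parted them in opposite directions. Across genes, log expression correlated between libraries of 1 group at r = 0.985 to 0.989, between P and R of 1 line at 0.939 to 0.957, and between lines at 0.691 to 0.757. Genes are not independent replicates, so these r carry no p. Mitochondrially encoded genes took 8.2% to 8.64% of the counts in HepG2 P and 9.42% to 9.85% in HepG2 R. In HuH they took 7.12% to 7.15% in P and 9.54% to 10.1% in R.

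The comparison of R with P in HepG2 asks which genes differ between the R and P groups of this line. ABCB1, which encodes the drug efflux pump P-glycoprotein, rose 162-fold, from 6.85 ± 0.218 CPM in P to 1111 ± 99.9 CPM in R (SD, n = 3; log2 7.34, SE 0.10, edgeR adjusted p = 9.02e-14). The aldo-keto reductases AKR1C1, AKR1C2 and AKR1B10, which reduce carbonyl compounds, rose 11.8-fold, 13.3-fold and 17.2-fold. UGT1A1, which glucuronidates bilirubin and drugs, rose from 0.501 ± 0.276 to 35.2 ± 9.45 CPM. SLC2A1, a glucose transporter, fell from 1285 ± 129 to 209 ± 27.1 CPM, and TYMS, the thymidylate synthase, fell from 129 ± 7.14 to 25.3 ± 2.75 CPM. Of 17063 genes tested, 8599 (50.4%) changed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4165 higher and 4434 lower in R. At least 2-fold changes were found in 1669 genes higher and 1515 lower. On log2(FPKM + 1) of the authors' FPKM, which scale by total count, the log2 changes of 12924 genes moved by a median of -0.15 against those of edgeR, through scaling and the added 1 together, and the calls split into 2583 higher and 5116 lower.

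**Figure D1:**
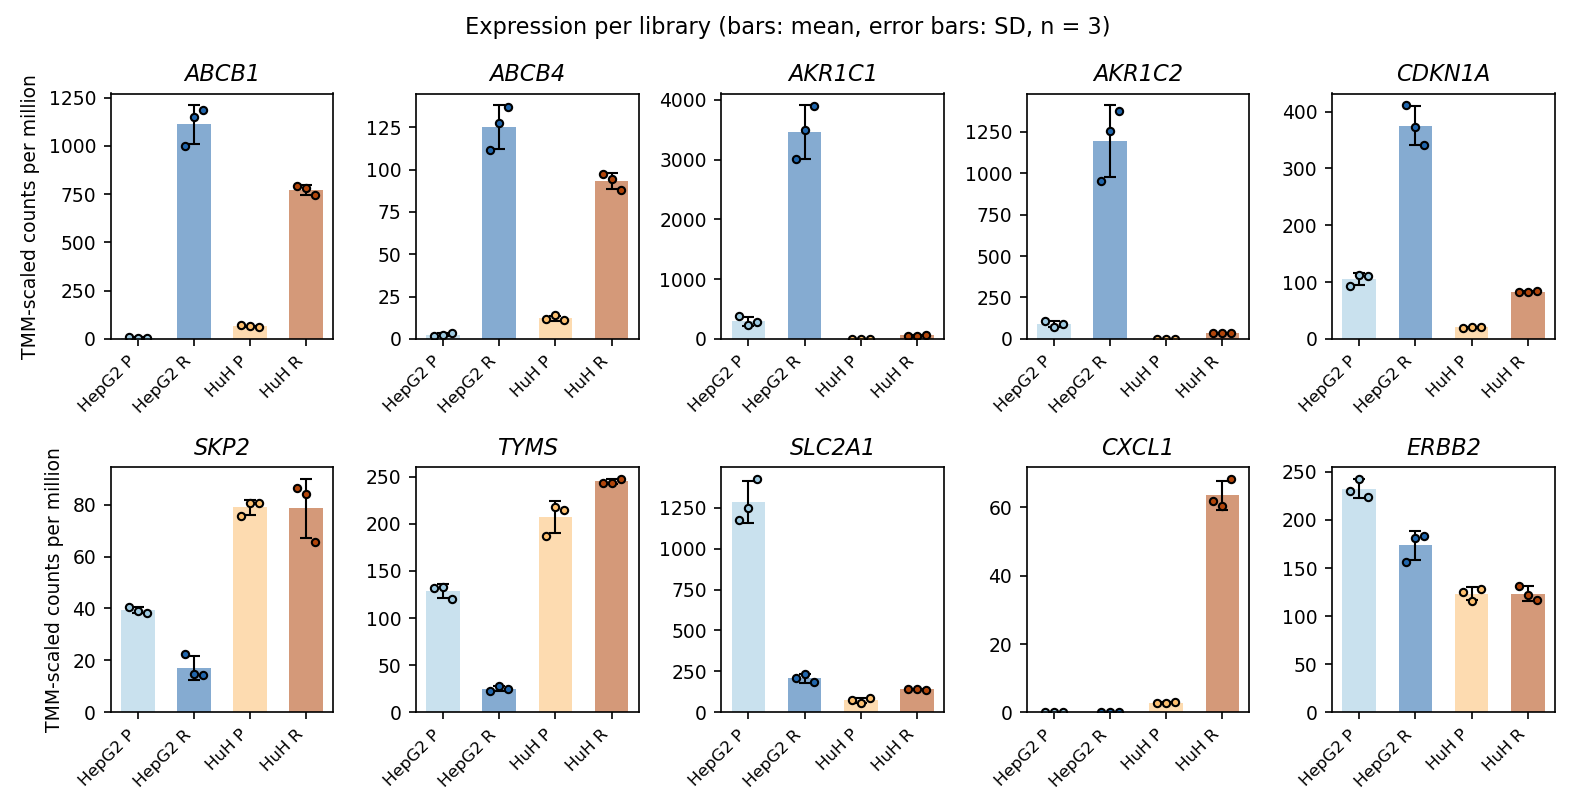
TMM-scaled CPM of 10 genes in the 12 libraries, with points for single libraries, bars for the mean of 3 libraries and error bars for the SD. ABCB1 rose from 6.85 to 1111 CPM in HepG2 and from 65.5 to 773 CPM in HuH, while SKP2 fell in HepG2 and stood at 78.9 and 78.6 CPM in HuH.

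Among genes that reached 5 CPM in the higher group and did not overlap between P and R, the largest rises in HepG2 included XIRP2. XIRP2, which encodes an actin-binding muscle protein, had 0 counts in all P libraries and 29.1 ± 3.74 CPM in R (SD, n = 3), at least 138-fold higher. NCALD, a neuronal calcium sensor, was likewise at 0 in P and at least 26.4-fold higher in R. PTPRJ, a receptor-type tyrosine phosphatase, rose from 0.127 ± 0.162 to 53.6 ± 8.16 CPM, and RUNDC3B rose from 0.247 ± 0.115 to 58.9 ± 3.18 CPM. RUNDC3B overlaps ABCB1, so reads of ABCB1 could have been counted in it. The non-coding gene RP11-1136G4.2 rose from 0.108 ± 0.101 to 29.9 ± 3.12 CPM. With 1 or 2 counts over the 3 P libraries, R levels were 9.99 ± 2.29 CPM for ARAP2, 14.5 ± 0.216 for LNX1, 7.70 ± 0.935 for ARLNC1 and 6.55 ± 0.669 for AC105411.1. Among the largest falls by the same rule, GPC6, a glypican of the cell surface, fell from 32.7 ± 3.88 to 0.0929 ± 0.0806 CPM. AL662884.1 stood at 27.0 ± 3.5 CPM in P and 3 counts in R, a ratio of 393 (95% interval 134 to 1907), and CHST9, a sulfotransferase, at 7.87 ± 1.85 CPM in P and 2 counts in R. AL928654.3, TNS4, SLC16A6, GGT5, ADGRL2 and SLC26A9 fell with log2 changes from -7.12 to -4.13. Fits of genes with few counts in a group moved when a library was left out: PTPRJ from 8.59 to 10.33 without HepG2 P replicate 3, RP11-1136G4.2 from 7.99 to 8.69 without HepG2 P replicate 1, and AL928654.3 from -7.12 to -7.78 without HepG2 R replicate 1. BLOC1S5-TXNDC5, a readthrough model over TXNDC5, went from 517 ± 256 CPM to 0 counts, at least 2380-fold lower, but the summed counts of it and TXNDC5 had a log2 change of only -0.22 (SE 0.04).

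Genes of cell division were lower in HepG2 R. Of 35 measured S and G2/M phase genes, 32 fell and 0 rose (32 and 0 adjusted over the list alone), with a median log2 of -1.11 (camera adjusted p = 2.58e-17, and adjusted p = 0.0791 with an estimated correlation). TYMS and the helicase subunits MCM2 and MCM5 had log2 changes of -2.35, -2.13 and -1.73. In the list of DNA repair and topoisomerases, 18 of 25 members fell and 2 rose (18 and 2 adjusted over the list alone), with a median of -0.71 (camera adjusted p = 4.04e-06, and adjusted p = 0.127 with an estimated correlation). FANCD2, of the Fanconi pathway, fell by 1.27 on the log2 scale, TOP2A, the topoisomerase of dividing cells, by 0.84, and XRCC5, the Ku80 subunit, by 0.84. Replication-dependent histones went the other way, with 8 of 12 members higher and 0 lower (9 and 0 adjusted over the list alone), a median of 1.10 (camera adjusted p = 0.00840, and adjusted p = 0.171 with an estimated correlation) and H2BC21 up from 1.43 ± 0.379 to 12.4 ± 1.37 CPM (SD, n = 3). Of 26 p53 target genes, 15 rose and 4 fell (15 and 4 adjusted over the list alone), with a median of 0.63 (camera adjusted p = 0.00182, and adjusted p = 0.164 with an estimated correlation). Among them, the cell cycle inhibitor CDKN1A rose from 106 ± 10.4 to 376 ± 35.0 CPM, the secreted stress factor GDF15 from 302 ± 76.2 to 2130 ± 609 CPM, and TP53INP1 from 33.1 ± 0.421 to 112 ± 10.8 CPM.

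Genes of detoxification and of cholesterol synthesis were higher in HepG2 R. Of 23 NRF2 target genes, 20 rose and 1 fell (20 and 1 adjusted over the list alone), with a median log2 of 1.03 (camera adjusted p = 3.81e-10, and adjusted p = 0.0699 with an estimated correlation). With the gene at 0 counts set aside, that median was 1.07. AKR1C1 and AKR1C2 are close copies between which reads could be split. In the list of cytochromes P450 and other phase I enzymes, 10 of 25 members rose and 2 fell (10 and 2 adjusted over the list alone), with a median of 0.85 (camera adjusted p = 0.0127, and adjusted p = 0.127 with an estimated correlation). On log2(FPKM + 1), 7 of 16 phase I members rose and 3 fell, with a median of 0.03. The carboxylesterases CES1 and CES2 rose with log2 changes of 1.96 and 1.52, and CYP1A1, induced by aryl hydrocarbons, rose from 5.41 ± 1.38 to 65.6 ± 7.90 CPM (SD, n = 3). In the cholesterol synthesis and uptake list, 19 of 24 members rose and 2 fell (19 and 2 adjusted over the list alone), with a median of 1.37 (camera adjusted p = 1.49e-08, and adjusted p = 0.127 with an estimated correlation). The regulator SREBF2 rose from 232 ± 12.4 to 671 ± 5.88 CPM, squalene synthase FDFT1 from 122 ± 11.8 to 347 ± 10.6 CPM, and MSMO1 from 65.9 ± 3.39 to 265 ± 39.4 CPM.

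Inflammatory, secretory and stress genes changed as well. In the list of inflammatory cytokines and NF-kB targets, 15 of 23 members rose and 1 fell in HepG2 (15 and 1 adjusted over the list alone), with a median log2 of 1.02, or 1.15 with members at 0 counts at their bound or set aside (camera adjusted p = 0.00121, and adjusted p = 0.164 with an estimated correlation). NFKB2 and the adhesion molecule ICAM1 rose with log2 changes of 1.22 and 1.02. Of 27 hepatocyte secreted proteins, 17 rose and 4 fell (17 and 5 adjusted over the list alone), with a median of 0.47 (camera adjusted p = 0.00670, and adjusted p = 0.171 with an estimated correlation). Complement C3 rose by 0.93 and fibrinogen FGB by 0.90 on the log2 scale, while haemopexin, HPX, fell from 15.5 ± 2.25 to 1.86 ± 0.137 CPM (SD, n = 3). In the unfolded protein and integrated stress response list, 17 of 27 members rose and 3 fell (17 and 6 adjusted over the list alone), with a median of 0.24 (camera adjusted p = 0.00838, and adjusted p = 0.171 with an estimated correlation). On log2(FPKM + 1), 12 of these 27 rose and 8 fell, with a median of 0.06, and of 26 secreted proteins 14 rose and 8 fell, with a median of 0.20. ATF4, ERN1 and VLDLR had log2 changes of 0.86, 1.73 and 1.68. Metallothioneins and heat shock proteins were lower, with 9 of 18 members down and 0 up (9 and 0 adjusted over the list alone) and a median of -0.55, or -0.53 with the member at 0 counts set aside (camera adjusted p = 0.00838, and adjusted p = 0.127 with an estimated correlation). The medians of other lists that passed moved by over 1.5-fold on log2(FPKM + 1) for NF-kB targets (to 0.39, with 12 of 22 higher), p53 target genes (to 0.35) and histones (to 0.42). The metallothionein MT1E fell from 6.24 ± 1.08 to 1.06 ± 0.390 CPM and the chaperonin HSPE1 from 138 ± 16.1 to 69.1 ± 3.95 CPM.

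The subjects of the series title were read in the same libraries. SKP2, the F-box subunit of a ubiquitin ligase, fell in HepG2 from 39.3 ± 1.15 to 17.1 ± 4.57 CPM (SD, n = 3; log2 -1.20, SE 0.16, edgeR adjusted p = 4.09e-05). In the list of SKP2 and its cell cycle partners, 2 of 16 members rose and 10 fell (2 and 10 adjusted over the list alone; camera adjusted p = 0.133), and its scaffold partner CUL1 fell from 63.3 ± 13 to 15.8 ± 0.826 CPM. ERBB2, the receptor that trastuzumab binds, fell from 232 ± 9.73 to 174 ± 15.2 CPM (log2 -0.42, SE 0.08, edgeR adjusted p = 8.11e-04). In the glycolysis and lactate list, 18 of 28 members fell and 3 rose (18 and 3 adjusted over the list alone), with a median log2 of -0.58, or -0.62 with the member at 0 counts set aside (camera adjusted p = 2.65e-04, and adjusted p = 0.164 with an estimated correlation). The glucose transporters SLC2A1 and SLC2A3 and the mutase PGAM1 had log2 changes of -2.62, -2.99 and -1.21.

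The other 17 lists did not pass the camera test in HepG2. Among genes of transport and conjugation, 6 of 14 ABC transporters rose and 5 fell (camera adjusted p = 0.371), with ABCG2 down from 36.3 ± 2.56 to 10.1 ± 1.24 CPM (SD, n = 3). The solute carriers for drug uptake had 6 of 14 higher and 4 lower (0.426), and the phase II conjugation enzymes 12 of 27 higher and 5 lower (0.144). Counts of higher and lower members were 10 and 6 of 24 receptor tyrosine kinases and their ligands (0.222), 5 and 6 of 19 liver transcription factors (0.641), 9 and 6 of 17 fetal liver, progenitor and biliary markers (0.403), and 10 and 6 of 27 genes of epithelial to mesenchymal transition (0.222). They were 6 and 7 of 26 apoptosis regulators (0.668), 13 and 8 of 25 genes of fatty acid synthesis and oxidation (0.133), 10 and 3 of 31 interferon-stimulated genes (0.120), 7 and 4 of 16 Wnt and beta-catenin target genes (0.222), and 7 and 8 of 18 tubulins and microtubule-associated proteins (0.535). Of 20 hypoxia-induced genes, 4 rose and 11 fell (0.0698), and this list passed without HepG2 P replicate 1 (0.00513) or without HepG2 R replicate 2 (0.0460). Among markers of other tissues, 5 rose and 2 fell of 11 gastric epithelium markers (0.426), 1 and 1 of 5 fibroblast and stellate cell markers (0.668), and 4 and 3 of 10 endothelial and blood cell markers (0.668). Of 13 mitochondrially encoded genes, 5 rose and 3 fell (0.159). Adjusted over the list alone, these counts were the same except for fatty acid genes, with 14 higher, and tubulins, with 8 higher. Median, mean and test differed in sign for liver transcription factors (-0.22, 0.01 and lower), apoptosis regulators (-0.01, 0.10 and higher) and tubulins (-0.52, 0.05 and lower).

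The comparison of R with P in HuH asks the same question of the other line. ABCB1 rose 11.8-fold, from 65.5 ± 3.26 CPM in P to 773 ± 25.4 CPM in R (SD, n = 3; log2 3.56, SE 0.08, edgeR adjusted p = 5.00e-11). REG1A, a secreted lectin of the regenerating gene family, had 0 counts in all P libraries and 128 ± 3.21 CPM in R, at least 795-fold higher. CXCL1, a neutrophil chemokine, rose from 2.85 ± 0.234 to 63.5 ± 4.32 CPM, and CES1, the main liver carboxylesterase, from 2.22 ± 0.0749 to 83.8 ± 1.06 CPM. NTS, the precursor of neurotensin, fell from 208 ± 12 to 5.83 ± 0.811 CPM. Of 17063 genes tested, 6808 (39.9%) changed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3929 higher and 2879 lower in R. At least 2-fold changes were found in 1749 genes higher and 448 lower. On log2(FPKM + 1) of the authors' FPKM, the log2 changes of 12986 genes moved by a median of -0.09 against those of edgeR, and the calls split into 2607 higher and 3577 lower.

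By the rule of 5 CPM and no overlap, other large rises in HuH included REG3A, a relative of REG1A, and SAMD5, both at 0 counts in P and at least 39.8-fold and 67.9-fold higher in R. STEAP4, a metalloreductase, had 2 counts over the 3 P libraries and 12.9 ± 0.664 CPM in R (SD, n = 3), a ratio of 382 (95% interval 106 to 3163). PKIA had 1 count in P and 7.27 ± 1.34 CPM in R, and DUOXA2, a maturation factor of an oxidase, 3 counts and 6.14 ± 0.549 CPM. NNMT, which methylates nicotinamide, rose from 1.11 ± 0.263 to 70.6 ± 15 CPM, LCN2, the iron-binding lipocalin, from 0.842 ± 0.388 to 44.2 ± 9.74 CPM, and NPNT, a matrix protein, from 1.10 ± 0.483 to 48.4 ± 1.04 CPM. The cadherin CDH11 rose from 0.162 ± 0.195 to 13.6 ± 0.442 CPM. Besides NTS, the largest falls by this rule were in ALDH1L2, a mitochondrial folate enzyme, from 7.81 ± 0.969 to 0.0821 ± 0.142 CPM, and in APOC4-APOC2, LINC01234, RASEF, TENM2, BEX1, FUT3, GRB7 and TOR4A, with log2 changes from -4.29 to -2.60. APOC4-APOC2 is a readthrough model over APOC2, which itself had a log2 change of -5.40. Without HuH R replicate 1, the change of ALDH1L2 moved from -6.61 to -10.06, and without HuH R replicate 3 to -5.99. Without HuH P replicate 2, that of CDH11 moved from 6.27 to 7.80.

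Inflammatory and interferon genes were higher in HuH R. In the list of inflammatory cytokines and NF-kB targets, 22 of 23 members rose and 0 fell (22 and 0 adjusted over the list alone), with a median log2 of 2.43 (camera adjusted p = 1.87e-15, and adjusted p = 0.0270 with an estimated correlation). The acute-phase protein ORM1 rose from 62.3 ± 3.68 to 185 ± 11.2 CPM and the cytokine IL32 from 11.5 ± 1.39 to 62.1 ± 5.67 CPM (SD, n = 3). Of 31 interferon-stimulated genes, 19 rose and 3 fell (20 and 3 adjusted over the list alone), with a median of 1.06 (camera adjusted p = 1.85e-04, and adjusted p = 0.0312 with an estimated correlation). The antiviral synthetases OAS1 and OAS3 rose with log2 changes of 3.38 and 3.54, and IFITM3, which blocks viral entry, with 1.82. In the list of apoptosis regulators, 13 of 26 members rose and 1 fell (13 and 1 adjusted over the list alone), with a median of 0.38 (camera adjusted p = 0.0327, and adjusted p = 0.0885 with an estimated correlation). The members that moved most included BIRC3, an inhibitor of apoptosis, with a log2 change of 4.53, and the pro-apoptotic PMAIP1 and BIK, with 2.29 and 2.25. Of 27 genes of epithelial to mesenchymal transition, 18 rose and 0 fell (18 and 0 adjusted over the list alone), with a median of 1.22 (camera adjusted p = 1.88e-06, and adjusted p = 0.0277 with an estimated correlation). LGALS1 rose from 1.99 ± 0.729 to 20.3 ± 0.574 CPM, N-cadherin, CDH2, from 51.9 ± 2.25 to 128 ± 4.56 CPM, and TGFB1 from 9.59 ± 1.73 to 34.8 ± 2.40 CPM.

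Mitochondrial, hypoxia and glycolysis genes were higher in HuH R too. Of 13 mitochondrially encoded genes, 12 rose and 0 fell (12 and 0 adjusted over the list alone), with a median log2 of 1.0 (camera adjusted p = 8.47e-10, and adjusted p = 0.0312 with an estimated correlation). MT-ND4, a subunit of respiratory complex I, rose from 4449 ± 145 to 12273 ± 302 CPM (SD, n = 3). Of 20 hypoxia-induced genes, 17 rose and 0 fell (17 and 0 adjusted over the list alone), with a median of 0.94 (camera adjusted p = 3.49e-06, and adjusted p = 0.199 with an estimated correlation). NDRG1, BNIP3 and the prolyl hydroxylase P4HA2 had log2 changes of 1.96, 1.37 and 1.24. In the glycolysis and lactate list, 17 of 28 members rose and 2 fell (17 and 3 adjusted over the list alone), with a median of 0.51 (camera adjusted p = 8.08e-04, and adjusted p = 0.130 with an estimated correlation). PGK1 rose from 415 ± 25.1 to 1062 ± 43.7 CPM and PFKFB4, which sets fructose 2,6-bisphosphate, from 25.7 ± 2.44 to 137 ± 5.54 CPM. In the unfolded protein and integrated stress response list, 17 of 27 members rose and 1 fell (18 and 1 adjusted over the list alone), with a median of 0.51 (camera adjusted p = 4.87e-05, and adjusted p = 0.0597 with an estimated correlation). The chaperone HSPA5 rose from 884 ± 37.9 to 1424 ± 2.13 CPM.

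ABC transporters and detoxification genes were also higher in HuH R, whereas solute carriers for drug uptake did not pass (camera adjusted p = 0.789). Of 14 ABC transporters, 8 rose and 0 fell (8 and 0 adjusted over the list alone), with a median log2 of 0.43 (camera adjusted p = 7.45e-04, and adjusted p = 0.0885 with an estimated correlation). ABCB4, a phospholipid transporter, rose from 12.2 ± 1.49 to 93.3 ± 4.85 CPM and the cholesterol exporter ABCG1 from 1.94 ± 0.583 to 19.5 ± 1.34 CPM (SD, n = 3). ABCB1 and ABCB4 are close copies between which reads could be split. Of 27 phase II conjugation enzymes, 19 rose and 3 fell (19 and 3 adjusted over the list alone), with a median of 1.03 (camera adjusted p = 4.87e-05, and adjusted p = 0.0344 with an estimated correlation). The glucuronosyltransferases UGT2A3 and UGT2B4 had log2 changes of 5.08 and 2.19. In the list of cytochromes P450 and other phase I enzymes, 10 of 25 members rose and 2 fell (10 and 2 adjusted over the list alone), with a median of 0.45 (camera adjusted p = 0.0333, and adjusted p = 0.130 with an estimated correlation). CYP2B6 rose from 12 ± 2.59 to 76.1 ± 3.22 CPM and CYP1A1 fell from 222 ± 36.7 to 43.1 ± 7.57 CPM, and without HuH R replicate 3 this list no longer passed (camera adjusted p = 0.0679). On log2(FPKM + 1), 6 of 16 phase I members rose and 2 fell, with a median of 0.07. Of 23 NRF2 target genes, 13 rose and 1 fell (13 and 1 adjusted over the list alone), with a median of 0.37 (camera adjusted p = 0.00145, and adjusted p = 0.130 with an estimated correlation). AKR1C2 rose from 0.961 ± 0.196 to 34.3 ± 1.65 CPM.

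Histones rose in HuH R as well, with 11 of 12 members higher and 0 lower (11 and 0 adjusted over the list alone), a median log2 of 1.64 (camera adjusted p = 8.04e-07, and adjusted p = 0.0312 with an estimated correlation), and the linker histone H1-2 up from 43.6 ± 2.49 to 126 ± 10.3 CPM (SD, n = 3). Of 35 S and G2/M phase genes, 12 fell and 3 rose (12 and 3 adjusted over the list alone), with a median of -0.13 (camera adjusted p = 0.00337, and adjusted p = 0.368 with an estimated correlation). The mitotic kinases AURKB and PLK1 had log2 changes of -1.02 and -0.64. Of 11 gastric epithelium markers, 7 rose and 2 fell (7 and 2 adjusted over the list alone), with a median of 1.09, or 1.12 with the member at 0 counts set aside (camera adjusted p = 0.0175, and adjusted p = 0.264 with an estimated correlation). Cathepsin E, CTSE, rose from 0.680 ± 0.105 to 9.12 ± 1.52 CPM and the intestinal cadherin CDH17 from 200 ± 7.30 to 574 ± 3.89 CPM, while lysozyme, LYZ, fell from 320 ± 10.3 to 133 ± 10.3 CPM. Among lists that passed in HuH, medians moved by over 1.5-fold on log2(FPKM + 1) for NF-kB targets (to 1.56), hypoxia-induced genes (0.58), ABC transporters (0.26), glycolysis (0.27), NRF2 target genes (0.24), apoptosis regulators (0.18), S and G2/M phase genes (-0.22), epithelial to mesenchymal transition (0.61, with 13 of 22 higher), interferon-stimulated genes (0.46) and phase II enzymes (0.48). SKP2 stood at 78.9 ± 2.98 and 78.6 ± 11.3 CPM and ERBB2 at 123 ± 6.67 and 123 ± 7.59 CPM in P and R, neither passing the test (edgeR adjusted p = 0.995 and 1).

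The other 15 lists did not pass the camera test in HuH. Counts of higher and lower members were 3 and 3 of 16 for SKP2 and its cell cycle partners (camera adjusted p = 0.614), 4 and 3 of 14 solute carriers for drug uptake (0.789), 10 and 5 of 24 receptor tyrosine kinases and their ligands (0.629), 13 and 7 of 27 hepatocyte secreted proteins (0.119), and 2 and 6 of 19 liver transcription factors (0.374). APOA2, an apolipoprotein among the secreted proteins, fell from 578 ± 31.8 to 116 ± 5.84 CPM (SD, n = 3), and MET, the receptor of hepatocyte growth factor, rose from 87.0 ± 4.79 to 369 ± 24.0 CPM. Of 17 fetal liver, progenitor and biliary markers, 7 rose and 3 fell (0.0727), and this list passed without HuH P replicate 2 (0.0466). The counts were 9 and 3 of 26 p53 target genes (0.253), 5 and 1 of 24 genes of cholesterol synthesis and uptake (0.155), 9 and 5 of 25 genes of fatty acid synthesis and oxidation (0.614), 3 and 6 of 16 Wnt and beta-catenin target genes (0.258), and 2 and 7 of 18 metallothioneins and heat shock proteins (0.229). They were 5 and 3 of 18 tubulins and microtubule-associated proteins (0.789), 5 and 6 of 25 genes of DNA repair and topoisomerases (0.255), 3 and 0 of 5 fibroblast and stellate cell markers (0.280), and 3 and 2 of 10 endothelial and blood cell markers (0.773). Adjusted over the list alone, the counts were the same except in 7 lists, with 11 and 6 receptor tyrosine kinases, 14 and 7 secreted proteins, 8 and 4 fetal markers, 9 and 4 p53 target genes, 3 and 1 cholesterol genes, 9 and 6 fatty acid genes and 3 and 1 fibroblast markers. Median and test differed in sign for solute carriers (0.12 and lower), Wnt target genes (0.06 and lower) and endothelial markers (0.04 and lower). With members at 0 counts set aside, the medians of solute carriers and endothelial markers were 0.09 and 0.49. For liver transcription factors, SKP2 partners and DNA repair genes, the mean was 0.08, 0.20 and 0.05 against medians of -0.08, -0.09 and -0.11.

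**Figure D2:**
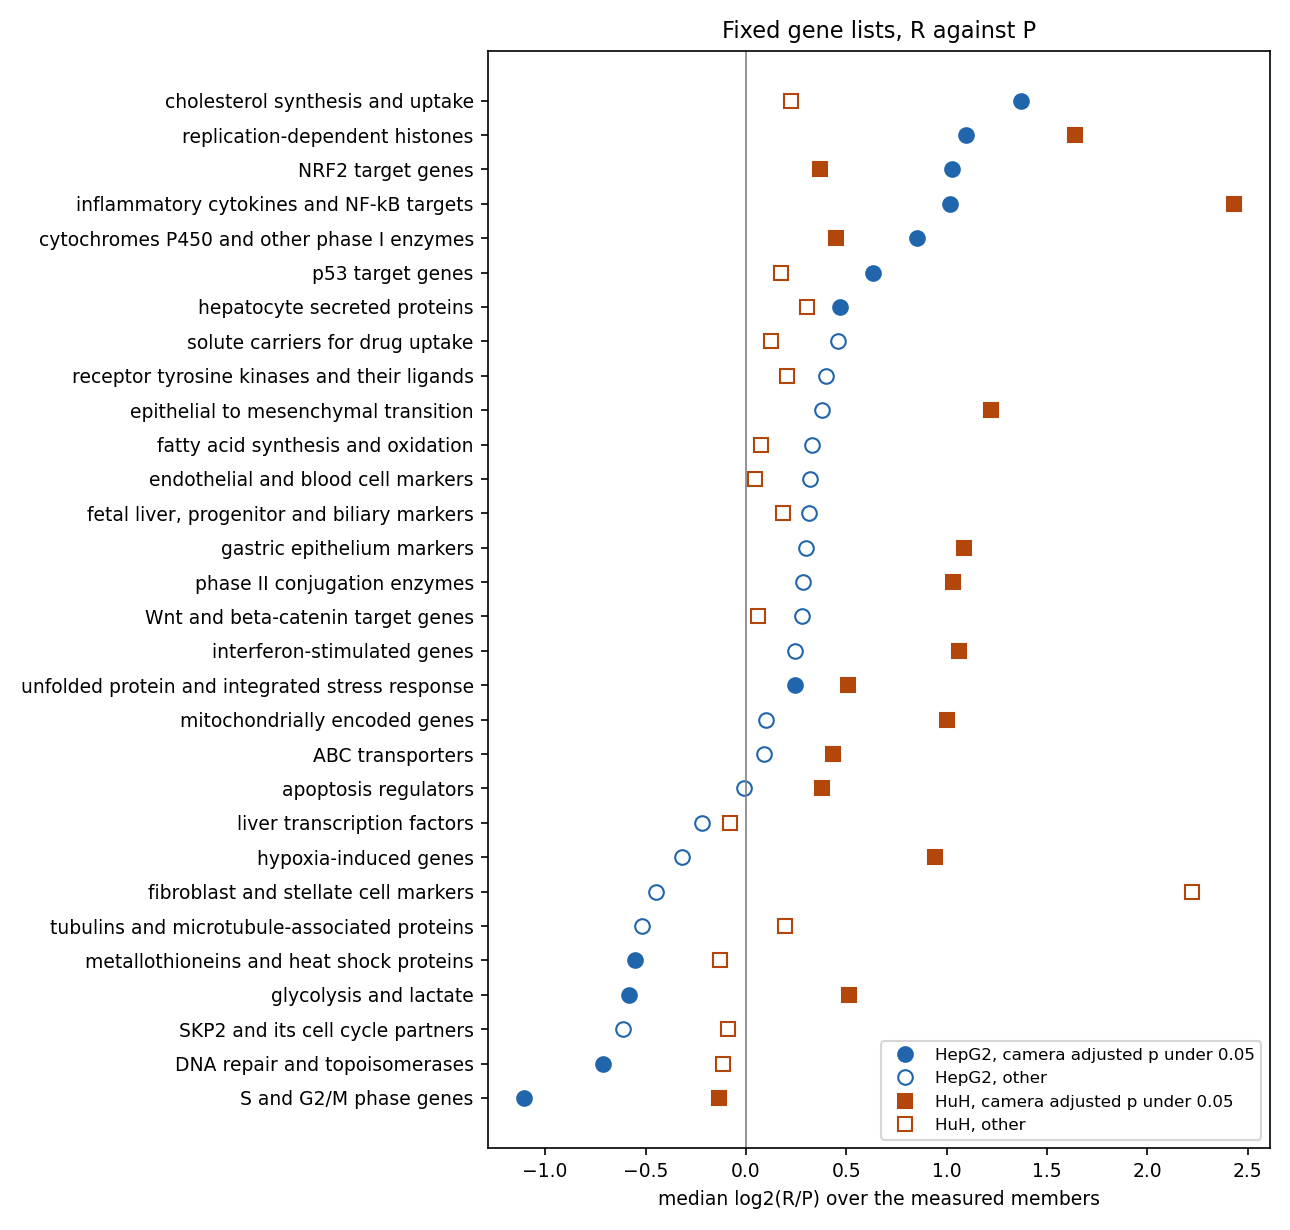
Median log2(R/P) over the measured members of each of the 30 gene lists in HepG2 (circles) and HuH (squares), filled where the camera adjusted p was under 0.05. Of these lists, 12 passed in HepG2 and 15 in HuH, and the glycolysis list lies at -0.58 in HepG2 and at 0.51 in HuH. With an estimated correlation, 0 lists passed in HepG2 and 6 in HuH, glycolysis not among them.

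The lines were then compared in how R differed from P. Genes of glycolysis, hypoxia and cell division changed differently in HuH and HepG2: SLC2A1 fell in HepG2 and rose from 72.6 ± 16.6 to 140 ± 0.949 CPM in HuH (SD, n = 3). CYP1A1 rose in HepG2 and fell in HuH, with a log2 difference of -5.96 (edgeR adjusted p = 1.18e-08). TYMS, SKP2 and the efflux pump ABCG2 changed more positively in HuH, by 2.59, 1.19 and 2.25 on the log2 scale, and ERBB2 by 0.42 (edgeR adjusted p = 0.00929). ABCB1 rose in both lines, by 3.78 less in HuH, where its P level was higher. In all, the change differed in 7501 genes, 4222 more positive and 3279 more negative in HuH, and by at least 2-fold in 2281 and 1515. By camera on this difference, chosen after the data were seen, 8 of the 30 lists passed and 0 with an estimated correlation (lowest adjusted p = 0.163). Glycolysis, S and G2/M phase, hypoxia, DNA repair, NF-kB target and mitochondrially encoded genes lay higher in HuH, and cholesterol and NRF2 target genes lay lower.

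Genes that changed the same way in both lines included ABCB1 and ABCB4, the aldo-keto reductases AKR1C1 and AKR1C2, and ADAM22, near ABCB1 on chromosome 7. AKR1C1 rose from 2.61 ± 0.0338 to 57.5 ± 12 CPM in HuH and from 294 ± 72.4 to 3463 ± 448 CPM in HepG2 (SD, n = 3). Among shared falls, the replication factor GINS4 had log2 changes of -1.64 and -1.62 in HepG2 and HuH, the chromatin protein HMGA2 -1.51 and -1.68, the Notch regulator NRARP -1.90 and -1.40, the ribosome factor UTP20 -2.37 and -1.31, and the uracil glycosylase UNG -1.61 and -1.26. Without HepG2 P replicate 3, the change of GINS4 in HepG2 was -0.93, and without HuH R replicate 3, that of HMGA2 in HuH was -2.36. CDKN1A rose in both, with log2 changes of 1.83 and 2.01. Both lines shared 1240 genes higher, where independent lists would share 959.1 (Fisher's exact test, p = 2.18e-31), and 972 lower, where they would share 748.1 (p = 2.15e-24). Another 1668 genes changed in opposite directions, where independent lists would give 1723.7. Genes are not independent replicates, so the p-values of Fisher's exact test, which takes them as independent, overstate the evidence for sharing. Across genes, the 2 log2 changes correlated at r = 0.0588. At least 2-fold changes were shared by 335 higher genes against 171.1 and by 35 lower genes against 39.8 (Fisher's exact test, p = 0.50). At this threshold 263 genes changed in opposite directions, also more than the 199.1 of independent lists. On FPKM the shared calls split into 674 higher and 1660 lower.

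The rise of ABCB1 lay within a run of neighbouring genes that rose in both lines. The run was chosen after its values were seen, by stepping outward from ABCB1 over tested genes called higher in both lines. It spans 86643914 to 88226993 on chromosome 7 (GRCh38), from GRM3 to SRI. All 14 tested genes taken into it rose in HepG2 and in HuH, which this rule largely fixed. AC003991.1, which starts inside the span, was not taken in, as it was not called in HepG2 (edgeR adjusted p = 0.080). The median log2 was 3.17 in HepG2, or 3.0 with GRM3 and SRI at their bounds, and 2.65 in HuH. The other 867 tested genes of chromosome 7 had medians of 0.00 and 0.20. DMTF1 rose from 29.3 ± 2.42 to 139 ± 6.31 CPM in HepG2 and from 28.1 ± 2.10 to 75 ± 2.98 CPM in HuH (SD, n = 3), and SLC25A40, a mitochondrial carrier, from 20.3 ± 1.2 to 102 ± 5.06 CPM and from 20.7 ± 1.54 to 165 ± 4.01 CPM. SRI, which encodes sorcin, rose from 29.4 ± 2.21 to 397 ± 10.6 CPM in HuH, but in HepG2 it had 0 counts in P and 0.224 ± 0.205 CPM in R.

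**Figure D3:**
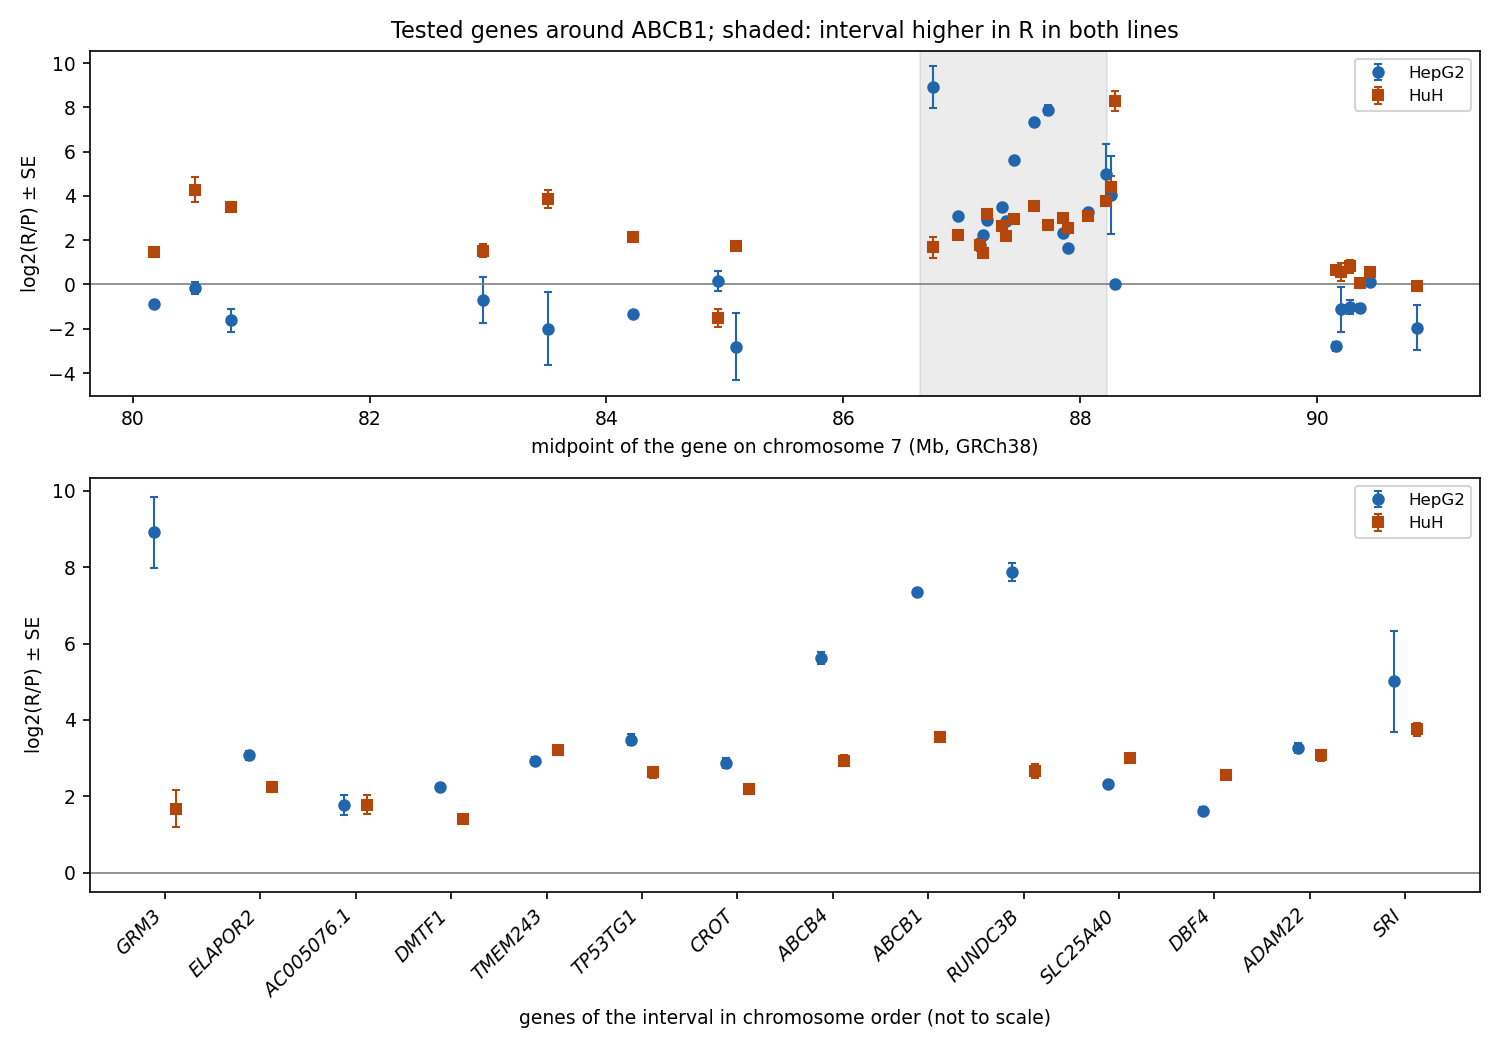
Log2(R/P) with its SE for tested genes around ABCB1 in HepG2 (circles) and HuH (squares), by position on chromosome 7 above and in gene order within the shaded interval below. The 14 genes of the interval were taken in because they were called higher in both lines, so all lie above 0. Fitted values were 1.63 to 8.91 in HepG2 and 1.42 to 3.76 in HuH. The highest, GRM3, had 0 counts in HepG2 P and is known only as at least 16.8-fold.

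Before any R comparison, the P groups of the lines differed widely. GC, the vitamin D-binding protein, and EFEMP1, a matrix protein, had 0 counts in HepG2 P and 283 ± 18.3 and 132 ± 9.36 CPM in HuH P (SD, n = 3), at least 1346-fold and 629-fold higher. INSIG1, which holds back sterol regulation, and NSD1, a histone methyltransferase, were also at 0 counts in HepG2 P, against 95.1 ± 17.2 and 141 ± 4.84 CPM in HuH P. CPLX2, HEPACAM, FREM1 and BPIFB2 had 0 counts in HuH P and 422 ± 22.1, 298 ± 32.6, 275 ± 39.3 and 170 ± 32.1 CPM in HepG2 P. A count of 0 shows only that no read was assigned to that gene model. Whether reads of these genes went to another model, or were left uncounted, was not tested. Between HuH P and HepG2 P, 12072 of 17063 genes differed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 6178 higher and 5894 lower in HuH, and 6874 by at least 2-fold, 3310 higher and 3564 lower. The calls split into 6045 higher and 3931 lower on log2(FPKM + 1). AC007192.1, which overlaps IFI30, was called higher in HuH (98.3 ± 87.7 CPM, 0 in HepG2 P, edgeR adjusted p = 0.0115), but its HuH level differed widely between libraries, and with the replicate number as a block it was not called (edgeR adjusted p = 0.177).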

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

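The test of the difference between the lines was fixed before the data were examined, while the list test of this difference, and every test of the readthrough model, were chosen only after the results were seen. These results are set apart because R differed from P in unlike ways in the lines, whose R labels also carry different numbers. The change differed between HuH and HepG2 in 7501 genes. When libraries were regrouped, 1 of 60 drawn splits, the real one, gave as many, and the highest other split gave 3694. Every other drawn split mixed P and R in at least 1 line, which removes that line's change. The regrouping thus argues against a chance assignment of libraries to P and R, but cannot test whether both lines changed alike. Of all 17063 genes tested, 1668 changed in opposite directions. The 208 named genes were picked in part for large changes. Among them, 156 had a change that differed between the lines and 47 changed in opposite directions. Among the latter, CYP1A1, which oxidises aromatic hydrocarbons, rose in HepG2 and fell in HuH, and SLC2A1, which imports glucose, did the reverse.

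BLOC1S5-TXNDC5 had the largest fitted difference, 29.91, going from 517 CPM to 0 counts in HepG2 and from 0 counts to 105 ± 180 CPM in HuH (SD, n = 3), and without HuH R replicate 3 the difference was 23.53. Its share of the summed counts with TXNDC5 was 77.2%, 26.4% and 69.8% in the HepG2 P libraries, 0% in HepG2 R, and 0.652%, 0% and 75.5% in HuH R. The summed counts had a log2 change of -0.22 in HepG2 and 0.35 in HuH. Assignment of the same reads to either of the overlapping models could thus account for most of the difference. A switch of transcript in HepG2 R remains open, because the share differed by 57.8 percentage points between P and R and by 50.9 points among the P libraries alone.

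Other genes with a more positive change in HuH were DACT2 (log2 difference 10.18), GPC6 (9.50), SAMD5 (9.27) and GALNT13 (9.12). DACT2, which dampens Wnt signals, and GALNT13, which starts mucin-type glycosylation, went to 0 counts in HepG2 R, at least 20-fold and 18.5-fold lower. Genes with a more negative change in HuH were XIRP2 (-13.19), RPS10-NUDT3 (-9.45), BEX1 (-8.99), LAMC3 (-8.16) and PTPRJ (-7.89). Where a group stood at 0 counts, the fitted difference depends on the fit and is not a bound. Without HepG2 P replicate 1 the difference of BEX1 was -11.03, without HepG2 P replicate 3 that of PTPRJ was -9.63, without HuH R replicate 3 that of XIRP2 was -17.64, and without HuH P replicate 2 that of RPS10-NUDT3 was -8.80. LAMC3, a laminin chain, lost its call without HuH P replicate 1 (log2 difference -5.68, edgeR adjusted p = 1).

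Of the lists that changed differently, S and G2/M phase genes had a camera adjusted p of 5.01e-11, and 29 of their 35 members were more positive and 1 more negative in HuH (32 and 1 adjusted over the list alone). For glycolysis and lactate, which take in SLC2A1 and PGK1, the camera adjusted p was 3.98e-07, for cholesterol synthesis and uptake 3.98e-07, and for mitochondrially encoded genes 4.03e-06. For hypoxia-induced genes it was 1.01e-05, for DNA repair and topoisomerases 9.49e-05, for inflammatory cytokines and NF-kB targets 0.00142, and for NRF2 target genes 0.0161. With an estimated correlation none of the 8 passed, the lowest adjusted p being 0.163.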

How the results depend on the processing

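Of 248 results for named genes, 245 were called, and no call of a gene or list was reversed under any alternative. A requirement of at least 2-fold left 3184 genes in HepG2, 2197 in HuH, 3796 for the difference, 6874 between the P groups and 370 shared. With the replicate number as a block, 8188, 6242, 7055 and 9716 genes were called and 1976 were shared, although deviations of libraries with the same number did not correlate (r from -0.04 to 0.02), so the number does not pair them. The block lost the call of AC007192.1 (edgeR adjusted p = 0.177). Leaving out single libraries gave 7722 to 8720 genes in HepG2, 5706 to 7093 in HuH, 6897 to 7285 for the difference, 11603 to 12310 between the P groups and 1854 to 2110 shared. Total gene counts stayed within 1.5-fold under DESeq2, its size factors, the other filters, the 6 libraries compared and FPKM. Counts by direction moved more on log2(FPKM + 1). There, genes higher in HepG2 went from 4165 to 2583, shared higher genes from 1240 to 674, and shared lower genes from 972 to 1660. Of 2976 tests of named genes with a library left out, 6 lost the call, all near the threshold except LAMC3. On log2(FPKM + 0.1), SLC29A2 in HuH lost its call (adjusted p = 0.0718), and on log2(FPKM + 1), PDGFRB in HuH did (adjusted p = 0.199). Of the 12 lists called in HepG2 and 15 in HuH, 0 and 6 passed with an estimated correlation, while fry called 27 and 23. Camera on log2(FPKM + 1), added after the data were seen, called 12 and 15, and leaving out libraries gave 12 to 13 and 14 to 16. Without a low count filter, SKP2 and its cell cycle partners (camera adjusted p = 0.0408) and hypoxia-induced genes (0.00844) passed in HepG2, and hepatocyte secreted proteins (0.0375), fetal markers (0.0487) and cholesterol genes (0.0494) in HuH. With 14538046 to 19972120 counts per library, changes of weakly expressed genes may have been missed.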

Other observations

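The tests of runs of neighbouring genes were chosen only after the results were seen. In HepG2 the lowest window of 15 neighbouring genes lay on chromosome 5 from PCDHB8 to PCDHGA6, in the clustered protocadherins of cell adhesion. Its median log2 was -1.70, barely below the lowest permuted median of -1.69 (permutation test over 1000 gene orders, p = 0.001, the smallest possible). In HuH the lowest lay on chromosome 10 from MAT1A to SNCG, with a median of -1.21 against a lowest permuted median of -1.11 (permutation test, p = 0.001). Permuting the order treats neighbours as separate genes, so reads shared between them could make these p-values too small. After the interval around ABCB1, the highest window in HepG2 ran from HFE to H4C8 on chromosome 6 (1.42), where histone genes cluster, and in HuH from MDFIC to TSPAN12 on chromosome 7 (1.99). Both lay below the highest permuted medians, 2.04 in HepG2 and 2.23 in HuH, and no p was computed for them.

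All tests of the run around ABCB1 were chosen only after the result was seen. The highest windows, GRM3 to AC003991.1 in HepG2 and ELAPOR2 to STEAP4 in HuH, covered most of the run, with fitted medians of 3.27 and 2.94 against highest permuted medians of 2.04 and 2.23 (permutation test, p = 0.001), which suggests a change acting on the neighbourhood, such as gained copies or altered chromatin, which a measure of DNA copy number would separate. Reads shared between ABCB1 and ABCB4 do not account for the rises of genes such as DMTF1 and SLC25A40, which overlap neither of them. In all, 12 other genes rose, of which only RUNDC3B overlaps ABCB1. The rule that built the run largely fixed this count, and SRI stood near the floor in HepG2. Scaling does not account for the run either, because the rest of chromosome 7 had a median of at most 0.20. In HuH, 7 of the 8 nearest tested upstream genes also rose, GNAI1, SEMA3C, PCLO, SEMA3E, SEMA3A and SEMA3D (log2 1.45, 3.51, 1.52, 3.84, 2.16 and 1.73) and CD36 (0.0473 ± 0.0819 to 1.12 ± 0.164 CPM, SD, n = 3), AC074183.2 fell (-1.50), and downstream AC003991.1 (4.38) and STEAP4 rose strongly and the more distant STEAP1 by 0.63. Farther downstream in HuH, CLDN12 rose by 0.54. In HepG2, GNAI1, SEMA3C, SEMA3A and STEAP1 fell (log2 -0.90, -1.63, -1.35 and -2.79), and the other upstream genes did not pass the test. Downstream in HepG2, CFAP69 and GTPBP10 also fell (log2 -1.02 and -1.06).

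For the histones, the tests of RNA without a poly(A) tail and of olfactory receptor genes in HuH were written before the result was seen, and the tests of cells in S phase and of olfactory receptor genes in HepG2 were chosen only after. Replication-dependent histone genes, whose RNA as a class mostly lacks a poly(A) tail, rose in both lines, H2BC21 and H1-2 among them. A general rise of RNA without a tail was tested on other such genes, of which only 6 of 46 listed could be tested. Their medians were -0.19 in HepG2 (1 rose, MALAT1, and 2 fell, RN7SL1 and RN7SL2) and -0.18 in HuH (1 rose, SNORD17, and 0 fell). They did not rise as a set, which argues against that cause, but so few genes cannot exclude it. More cells in S phase do not account for the histone rise in HepG2, where S and G2/M phase genes had a median of -1.11. In HuH their median was only -0.13, with 12 lower and 3 higher (camera adjusted p = 0.00337, and adjusted p = 0.368 with an estimated correlation). The list thus leaves S phase open in HuH. Genomic DNA could not explain the histone rise in HuH (olfactory receptor ratio 0.796). In HepG2 the ratio was 1.70 without the OR51B genes and 7.63 with them, so the ratio alone left a contribution open. The 428 genes without OR51B together reached only 1.64 ± 0.484 CPM in P and 2.79 ± 0.834 CPM in R (SD, n = 3). The histone list summed to 30.4 ± 3.41 and 67.8 ± 1.49 CPM. These amounts argue against genomic DNA as the main source of the histone rise in HepG2. Measuring histone RNA with and without a poly(A) tail separately would test whether polyadenylated histone transcripts rose.

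The regrouping tests were written before the results were seen. With 10 possible splits, a share under 0.05 cannot be reached, so they say only that 1 split, the real one, gave as many as the real 8599 genes in HepG2, 6808 in HuH and 12072 between the P groups, against 1, 2 and 0 for the highest others. For the lists, the real 12 and 15 stood against 9 and 11. The 2212 shared genes were reached by 1 of 60 drawn splits, the real one, against 0 for the highest other. Every other drawn split mixed P and R in at least 1 line, so few or no shared genes could be found in it.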
